A study of Mus musculus with 6 samples.

How the data were processed

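Bulk RNA-seq was measured in CD4 T cells sorted from the lamina propria of the mouse colon. Per the labels, naive CD4 T cells from the spleen of mice carrying a GFP reporter for Tcf7 were transferred into Rag1 knockout hosts, which lack T and B cells of their own, and colitis followed. GFP-positive cells (TCF7-positive) and GFP-negative cells (TCF7-negative) were then collected. There were 3 libraries of each kind, 6 in all, and groups and replicate numbers were taken from the sample titles. The labels do not say that the replicates came from separate mice, so p-values measure only the spread between these samples, part of which may be technical.

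Per the labels' protocols, RNA was reverse transcribed with oligo-dT and random primers, the cDNA was amplified by PCR and tagged with a transposase-based kit, and libraries were read in pairs. That procedure does not record the strand and has no molecular identifiers. Reads of genes that overlap on opposite strands therefore cannot be told apart, and floors and intervals from counts cover counting error only. Because the cDNA was amplified from a sorted population, counts of weakly expressed genes carry amplification noise that the spread between libraries includes.

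The authors deposited a table of raw counts per gene and a table of TPM. Per the submitters' processing notes, fastp 0.23.3, STAR 2.7.10b, SAMtools 1.17 and deepTools 3.5.1 were used with the mm10 build; the role and settings of each, the read counter and the gene annotation are not given in the sources used here. The deposited counts are whole numbers that sum to between 4309500 and 7462076 per library. The labels speak of a minimum of uniquely mapped reads per sample that lies above these totals. In the deposited TPM table each column has the same sum, and TPM divided by count was constant per gene up to a factor per library. Genes of the count table that the TPM table lacks, ribosomal RNA and transfer RNA genes among them, held between 3.65% and 7.82% of the counts. All value columns of both tables could be matched to a sample.

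Of 55335 gene identifiers, 54587 matched GENCODE M21 with their version and 55154 matched with or without it. Coordinates are those of M21 on mm10 (GRCm38), 1-based. Tcf7 was matched without its version. Symbols are those of the count table.

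The main test was the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3) on the deposited counts, with robust dispersions, TMM factors, edgeR's default expression filter by group (minimum count 10) and the group as the only term. The filter kept 11074 genes. P-values were adjusted by Benjamini-Hochberg and the threshold was 0.05. CPM values are relative to the TMM-scaled total of the tested genes, and a gene's standard error (SE) was derived from its log2 fold change and F. Log2 fold changes are GFP-positive minus GFP-negative throughout.

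Sets of genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 30 lists. The lists were fixed before the data were examined and covered T cell states, metabolism, stress after tissue dissociation, T cell identity and 8 other kinds of cell. Of their 514 entries, 513 were found in the count table. Members were counted by the edgeR test adjusted over all genes and adjusted over the list alone. Camera with an estimated correlation and fry were run beside it. Other-cell markers were also summed per library as a percent of counts and compared by a two-sided exact permutation test, whose smallest possible p with 3 against 3 is 0.1.

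Named genes followed a rule set in advance. It took Tcf7, a fixed panel of 26 T cell genes, up to 8 rises and 8 falls with the largest fold among genes past the threshold with a mean of at least 5 CPM and no overlap between groups (gene-model names left out), and up to 4 members of each list with the smallest adjusted p. Some genes the rule takes are not reported here. Genes outside the rule are said to be so where they appear.

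Both tests were tested on simulated data drawn from the real means, library sizes and dispersions of this comparison. In counts for 10735 genes, edgeR recovered 31 of 96 genes changed 2-fold and 62 of 94 changed 4-fold, with 7 unchanged genes among 100 calls. DESeq2 recovered 36 and 71 with 17 unchanged genes among 124 calls, and limma-voom 26 and 55 with 5 among 86. A list shifted 2-fold was called by camera and no other list was. In that simulation genes vary independently of each other.

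Alternatives planned before the data were examined were RLE factors, library size alone, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, limma on log2(TPM + 1) and log2(TPM + 0.1) with a mean of at least 1 TPM, the former also unfiltered, a fold minimum, a threshold of 0.01, the estimated correlation, fry, and leaving out each library. No pair of libraries was a duplicate, as the smallest chi-square per degree of freedom between replicates was 10.7. The deposited sheet of sample names was not used.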

Results

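Colon CD4 T cells were compared between 2 sort gates, 3 GFP-positive against 3 GFP-negative libraries. The GFP-positive gate reports the locus of Tcf7, which encodes TCF1, a transcription factor of naive, memory and stem-like T cells, and the labels call the GFP-negative cells effector T cells. Total counts were 5183794, 4309500 and 4571460 in GFP-negative replicates 1 to 3 and 5576707, 4408385 and 7462076 in GFP-positive replicates 1 to 3. A gene with 3 counts stood at 0.43 to 0.69 CPM in these libraries.

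The comparison asked how T cells with and without activity of the Tcf7 reporter differed in the inflamed colon. GFP-positive cells had more mRNA of Id3, an inhibitor of E proteins linked to memory T cells, of Socs3, a feedback inhibitor of cytokine signalling, and of Scml4, a Polycomb-group gene. Lag3, an inhibitory receptor of activated T cells, was lower in them. Id3 rose from 14.3 ± 5.49 to 68.9 ± 22.6 CPM (SD, n = 3 each), Socs3 from 130.4 ± 9.95 to 319.8 ± 63.4 CPM and Scml4 from 13.8 ± 2.04 to 54.1 ± 7.04 CPM. Lag3 fell from 58.9 ± 21.02 to 14.5 ± 1.499 CPM. By edgeR's quasi-likelihood test, 12 of 11074 genes passed an adjusted p of 0.05, 4 higher and 8 lower in GFP-positive cells.

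Tcf7 (ENSMUSG00000000782.16, chromosome 11, 52252371 to 52283014, minus strand) had 187 ± 48.4 CPM in GFP-positive and 111 ± 35.7 CPM in GFP-negative libraries (SD, n = 3 each), on 325 to 1371 counts per library. The ratio of the means was 1.69, and the groups did not overlap by a narrow margin, the lowest GFP-positive library lying at 140.8 CPM and the highest GFP-negative one at 140.5 CPM. The log2 fold change of Tcf7 was 0.75 ± 0.26 (SE), with an adjusted p of 0.367 in edgeR's test over all genes, so it was not called there. Over the stem and memory list alone, Tcf7 passed the threshold.

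Among the genes that rose, Id3 (chromosome 4, 136143497 to 136145755) had a log2 fold change of 2.27 ± 0.35 (SE; edgeR adjusted p = 0.0285). Scml4 (chromosome 10, 42860370 to 42960780) changed by 1.97 ± 0.25 and Socs3 (chromosome 11, 117966079 to 117970047) by 1.29 ± 0.17, each with an edgeR adjusted p of 0.0125. The lincRNA Gm2682 (chromosome 15, 60120540 to 60187408), named here outside the rule because only 4 genes rose, changed by 1.59 ± 0.24 (edgeR adjusted p = 0.0262). Lag3 (chromosome 6, 124904361 to 124911705) had a log2 fold change of -2.02 ± 0.29 (edgeR adjusted p = 0.0165).

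The other genes that fell were of several kinds. Tmpo, which encodes lamina-associated polypeptides of the nuclear envelope, fell from 182 ± 33.5 to 65.8 ± 13.9 CPM, and Pcbp1, which encodes a poly(C)-binding protein, from 316 ± 56.4 to 103 ± 30.9 CPM. Arf6, a small GTPase of membrane traffic, fell from 267 ± 3.49 to 105 ± 34.9 CPM. Rnpepl1, an aminopeptidase-like gene, had a log2 fold change of -1.79 ± 0.26 (SE), and Ermn, which encodes the cytoskeletal protein ermin, had -1.21 ± 0.16. Ppp1cc, a catalytic subunit of protein phosphatase 1, changed by -1.15 ± 0.19 and the kinase gene Stk24 by -0.98 ± 0.13. Exons of Ermn, Tmpo, Pcbp1 and Arf6 overlap exons of a gene on the other strand, so their counts may include reads of Galnt5, Gm26765, 1600020E01Rik and Gm9887 respectively.

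All 12 genes had CPM values that did not overlap between the groups. Over all tested genes, 1777 (16.0%) did not overlap, where chance gives 10%, and 1138 had an unadjusted p below 0.05 where 553.7 would be expected. With the expression filter applied anew, the count of calls was 1 without GFP-negative replicate 1, 3 without GFP-negative replicate 2, 0 without GFP-negative replicate 3, 0 without GFP-positive replicate 1 and 0 without GFP-positive replicate 2, none of them among the 12; on the genes of the full data it was 10, 5, 11, 0 and 3. Without GFP-positive replicate 3 it was 42, all 12 included.

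**Figure D1:**
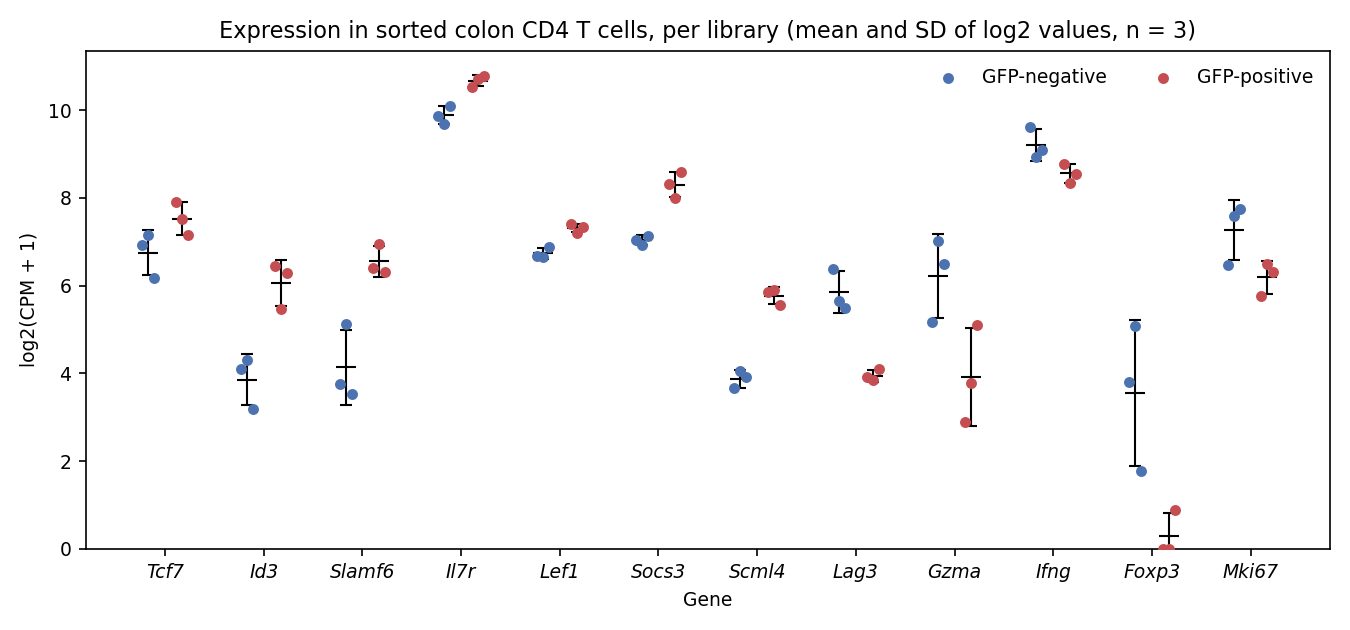
Log2(CPM + 1) of 12 genes in each library, with blue points for GFP-negative and red points for GFP-positive libraries and black bars for the mean and SD of the log2 values (n = 3 each). Id3, Socs3, Scml4 and Lag3 passed the test, the other 8 genes did not, and the Foxp3 values of GFP-positive replicates 1 and 2 lie at 0.

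GFP-positive replicate 3 stood apart from the other 5 libraries. It had 17119 genes with at least a count against 14538 to 15346 in the others. Its Pearson r of log2 CPM across genes with the others was 0.879 to 0.894, where pairs of the other 5 reached 0.897 to 0.935; these are correlations across genes, which are not independent replicates. Markers of myeloid cells held 0.741% of its counts and 0.0147% to 0.0212% of those of each other library. Lyz2, the lysozyme of macrophages and neutrophils, stood at 4217 CPM there and at 65.8 to 100.4 CPM in the others. Antigen-presenting cell markers, Cd74 and MHC class II genes among them, held 0.662% of its counts. Natural killer and innate lymphoid markers, mostly Tyrobp and Fcer1g, which myeloid cells also express, held 0.0813%. Epithelial markers held 0.0591% and the stromal and endothelial list 0.0433% of its counts. In that list Dcn stood at 221.7 CPM and Col3a1 at 97.2 CPM in this library. Its endothelial genes Cdh5, Kdr and Vwf were at 0 there, and Pecam1, at 65.3 CPM, lay within the range of the other libraries.

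Between the gates, markers of all 8 other kinds of cell held 0.573% ± 0.882 of counts in GFP-positive and 0.0952% ± 0.0122 in GFP-negative libraries (SD, n = 3 each; two-sided exact permutation p = 1, adjusted p = 1 over 9 sums). Without GFP-positive replicate 3 the difference changed from 0.478 to -0.0315 percentage points. Cd8a, a marker of CD8 T cells, had 27.2 ± 17.9 CPM in GFP-positive and 66.7 ± 42.2 CPM in GFP-negative libraries. Cd8b1, the other gene of that list, had 3.76 ± 1.94 and 5.09 ± 4.51 CPM, and Ighm, an immunoglobulin gene, 9.84 ± 0.987 and 31.9 ± 29.8 CPM. None of these passed edgeR's test (adjusted p = 0.634, 0.901 and 0.41).

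**Figure D2:**
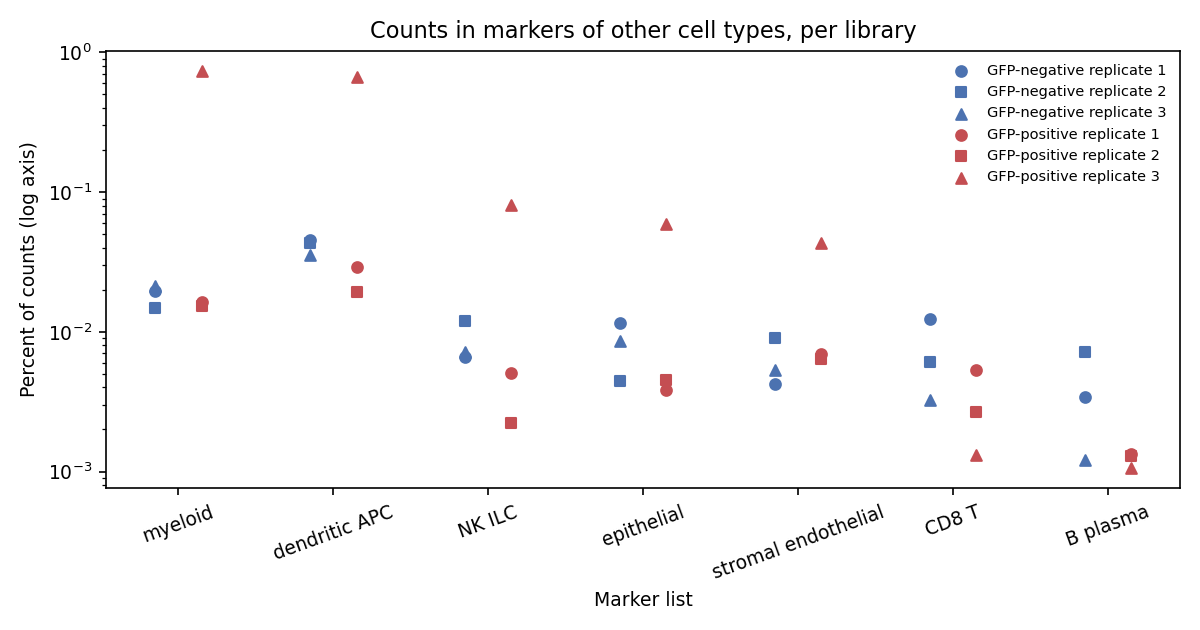
Percent of each library's counts in 7 lists of marker genes of other cell types, on a log axis, with symbols for replicates and colours for the gates. GFP-positive replicate 3 lies above every other library for myeloid, antigen-presenting, natural killer, epithelial and stromal markers, reaching 0.741% for the myeloid list; the erythroid list is not drawn because it is at 0 in 2 libraries.

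Genes of stem-like and memory T cells were higher as a group in the GFP-positive gate. Of 22 tested members, 19 had a positive log2 fold change, with a median of 0.76. Tcf7, Il7r, Id3, Slamf6, Nsg2, Lef1, Klf3, Ccr7, S1pr1 and Bcl2, 10 in all, rose when adjusted over the list alone, and adjusted over all genes only Id3 did. Slamf6, a receptor that marks stem-like T cells, had 94.97 ± 24.6 CPM against 19.0 ± 12.9 CPM (SD, n = 3 each), and Il7r, the receptor of the survival cytokine IL-7, had 1639.5 ± 144.8 against 950.4 ± 135.1 CPM. S1pr1, which directs exit from tissue, had 208 ± 44.8 against 95.6 ± 26.9 CPM, and Lef1, a relative of Tcf7, had 159 ± 11.1 against 106 ± 8.93 CPM. The list was called by camera (adjusted p = 1.07e-07), and its adjusted p was 0.17 with an estimated correlation.

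All 6 tested targets of Wnt signalling had positive log2 fold changes (median 0.53; camera adjusted p = 0.0142), and the adjusted p was 0.563 with an estimated correlation. Adjusted over the list alone Tcf7, Lef1 and Myc rose, and none did over all genes. Tcf7 is the gene of the sorting reporter, so its direction is not independent of the gate. Without Tcf7, a test chosen after seeing the data, the adjusted p was 0.0438 for the other 5 Wnt targets (0.563 with an estimated correlation) and 2.56e-07 for the other 21 stem and memory genes (0.151 with an estimated correlation). The adjusted p of the list was 0.0647 without GFP-positive replicate 2, 0.245 with no filter and 0.0619 with a filter of 1 CPM in 3 libraries.

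Cell cycle genes were lower in the GFP-positive gate. All 35 had a negative log2 fold change, with a median of -1.14. The median was -1.46 without GFP-negative replicate 1 and -0.79 without GFP-negative replicate 3. Mki67, a marker of proliferating cells, had 73.9 ± 18.4 CPM in GFP-positive and 164 ± 66.6 CPM in GFP-negative libraries (SD, n = 3 each). Its groups overlapped, with 88.2 CPM in GFP-negative replicate 1 and 89.7 CPM in GFP-positive replicate 2. Tyms, thymidylate synthase, had 37.9 ± 3.92 and 88.6 ± 27.7 CPM. Mki67, Top2a, Cdk1 and Uhrf1 were among 15 that fell when adjusted over the list alone, and adjusted over all genes 0 did. Camera called the list (adjusted p = 2.13e-15), while the adjusted p was 0.563 with an estimated correlation, and the mean log2 CPM of the list was 5.08, 5.99 and 6.40 in GFP-negative and 4.32, 4.92 and 4.98 in GFP-positive replicates 1 to 3.

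By camera at the preset correlation, cytotoxic genes, inhibitory receptors and regulators of effector cells were also lower as groups. With an estimated correlation none of these lists was called. In the cytotoxic list 18 of 19 tested members were negative, with a median of -0.32 (camera adjusted p = 0.0022); the adjusted p was 0.563 with an estimated correlation. Adjusted over the list alone Nkg7, Klrg1, Klrc1 and Gzmk fell, and over all genes 0 did. Klrg1, a receptor of terminally differentiated cells, had 16.6 ± 3.03 CPM against 47.2 ± 20.6 CPM (SD, n = 3 each). The median of the list was -0.53 without GFP-negative replicate 3. Of the CD8 T cell markers, Cd8a stood at 27.2 ± 17.9 against 66.7 ± 42.2 CPM and Cd8b1 at 3.76 ± 1.94 against 5.09 ± 4.51 CPM. Neither passed edgeR's test over all genes (adjusted p = 0.634 and 0.901). The natural killer list was lower without GFP-positive replicate 3 (camera adjusted p = 0.0144, and 0.624 with an estimated correlation). Tyrobp, an adaptor of natural killer and myeloid cells, had 15.2 and 4.60 CPM in GFP-positive replicates 1 and 2 and 26.1 to 35.2 CPM in GFP-negative libraries. Granzyme genes spread widely, with Gzma at 17.4 ± 14.1 against 83.8 ± 46.7 CPM and Gzmb at 148 ± 63.2 against 301 ± 115 CPM.

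Inhibitory receptors moved in both directions. Of 16 tested, 10 were negative, and adjusted over the list alone Lag3, Pdcd1, Ctla4, Klrg1, Klrc1 and Cd160 fell while Btla and Lilrb4a rose; over all genes only Lag3 fell. Pdcd1, which encodes PD-1, had 43.6 ± 10.5 against 83.4 ± 30.5 CPM (SD, n = 3 each), and Btla had 83.9 ± 24.1 against 44.6 ± 11.3 CPM. The list was called lower by camera (adjusted p = 0.0461), with an adjusted p of 0.563 with an estimated correlation. Its adjusted p was 0.165 without GFP-negative replicate 1, 0.0775 without GFP-negative replicate 2, 0.137 without GFP-positive replicate 1 and 0.0848 without GFP-positive replicate 2. Havcr2, which encodes TIM-3, stood at 12.7 ± 15.9 against 50.0 ± 19.5 CPM. Its value of 31.0 CPM in GFP-positive replicate 3, the library with myeloid transcripts, exceeded the 4.68 and 2.30 CPM of replicates 1 and 2.

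Among 15 effector regulators 11 were negative (median -0.19; camera adjusted p = 0.0142), and the adjusted p was 0.563 with an estimated correlation. Adjusted over the list alone Tbx21, Ikzf3 and Prdm1 fell, and over all genes 0 did. Prdm1, which encodes Blimp-1, had 103 ± 19.7 against 162 ± 6.02 CPM (SD, n = 3 each), and Tbx21, the Th1 regulator T-bet, had 112 ± 16.7 against 161 ± 22.3 CPM. Id2, another effector regulator, had 1047 ± 80.9 against 947 ± 206 CPM. The adjusted p of the list was 0.0653 without GFP-negative replicate 1 and 0.123 without GFP-positive replicate 1, and its median was -0.33 without GFP-positive replicate 3.

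Genes of regulatory T cells were lower as a group, 14 of 16 with a negative log2 fold change (median -0.22; camera adjusted p = 0.0142). The adjusted p was 0.661 with an estimated correlation, 0.175 without GFP-negative replicate 2 and 0.137 without GFP-positive replicate 1. The median was -0.39 without GFP-negative replicate 1 and -0.57 without GFP-positive replicate 3. It was -0.45 without GFP-negative replicate 3 and -0.48 without GFP-positive replicate 2, where 17 members passed the filter. On the same 16 members these medians were -0.35 and -0.38. Adjusted over the list alone Foxp3, Tnfrsf9, Klrg1 and Capg fell, and over all genes 0 did. Foxp3, the defining factor of regulatory T cells, stood at 13.0, 33.0 and 2.41 CPM in GFP-negative replicates 1 to 3, at 0 in GFP-positive replicates 1 and 2 and at 0.861 CPM in replicate 3 (edgeR adjusted p = 0.18 over all genes). A count of 0 allows up to 0.52 and 0.69 CPM of Foxp3 in GFP-positive replicates 1 and 2. Il10 was also low, at 0.794 ± 1.18 against 4.43 ± 2.51 CPM.

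Helper T cell lineage lists were not called. In the Th1 list 13 of 20 were negative (camera adjusted p = 0.168), and adjusted over the list alone Tbx21, Ifng and Nkg7 were among those that fell while Cxcr3 rose. Ifng had 379 ± 55.8 CPM in GFP-positive and 604 ± 158 CPM in GFP-negative libraries (SD, n = 3 each), and Cxcr3 had 358 ± 20.6 and 248 ± 14.7 CPM. In the Th17 list 9 of 16 were negative (camera adjusted p = 0.791) and none passed over the list alone. Il17a stood at 19.2 ± 20.7 and 56.4 ± 54.4 CPM and Il22 at 137 ± 57.6 and 133 ± 54.2 CPM. The Th2 list (adjusted p = 0.755; Areg fell over the list alone) and the follicular helper list (adjusted p = 0.672) were not called either. In the latter Slamf6 and Btla rose and Pdcd1 and Il21 fell over the list alone, and Bcl6 had 104 ± 6.18 and 104 ± 7.30 CPM.

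Among 26 tested cytokine genes 15 were negative (camera adjusted p = 0.362). Adjusted over the list alone Il2 rose, at 22.7 ± 2.11 against 8.88 ± 2.20 CPM (SD, n = 3 each), and Csf1, Areg and Ifng fell, Csf1 from 96.7 ± 20.2 to 44.4 ± 10.5 CPM; adjusted over all genes 0 did. Without GFP-negative replicate 3 the cytokine list had a camera adjusted p of 0.043, and 0.427 with an estimated correlation. In the homing list (camera adjusted p = 0.368) S1pr1, Itga4, Ccr7 and Cxcr3 rose over the list alone. In the residency list (camera adjusted p = 0.121) Prdm1 fell over the list alone. This list had an adjusted p of 0.0309 without GFP-negative replicate 3, 0.00872 without GFP-positive replicate 2 and 0.0491 with no filter. With an estimated correlation these were 0.649, 0.629 and 0.675. Genes induced by T cell receptor signalling went both ways, 8 positive and 9 negative (camera adjusted p = 0.697), and Tnfrsf9 fell over the list alone.

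Ribosomal protein genes were higher as a group, 75 of 78 with a positive log2 fold change and a median of 0.34 (camera adjusted p = 1.07e-07), and the adjusted p was 0.661 with an estimated correlation. The mean log2 CPM of the list was 8.99, 8.86 and 9.26 in GFP-negative replicates 1 to 3 and 8.86, 9.54 and 9.62 in GFP-positive ones, so that GFP-positive replicate 1 had the lowest value of the 6 libraries. The median was 0.23 without GFP-positive replicate 3, and no member passed over the list alone. Rps27 had 3472 ± 617 CPM in GFP-positive and 2171 ± 301 CPM in GFP-negative libraries (SD, n = 3 each). Interferon response genes were higher as well, 22 of 25 positive (median 0.44; camera adjusted p = 0.00637), with an adjusted p of 0.661 with an estimated correlation. Rtp4 rose when adjusted over the list alone, at 52.8 ± 23.1 against 21.6 ± 5.25 CPM. The interferon list had an adjusted p of 0.0521 without GFP-positive replicate 1 and 0.116 without GFP-positive replicate 3, the library with myeloid transcripts. Its median was 0.16 without that library and 0.28 without GFP-negative replicate 3.

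Genes of stress after tissue dissociation, which can be a sign of handling, were higher as a group too. Whether handling raised these genes was not tested, and Egr1 is also in the T cell receptor list. All 18 were positive (median 0.32; camera adjusted p = 0.0022), with an adjusted p of 0.661 with an estimated correlation and 0.0904 without GFP-negative replicate 3. The mean log2 CPM of the list was 9.65, 9.25 and 8.96 in GFP-negative and 9.70, 9.58 and 9.69 in GFP-positive replicates 1 to 3. The median was 0.20 without GFP-negative replicate 3 and 0.48 without GFP-negative replicate 1. Fos, an immediate early gene, had 643 ± 198 CPM in GFP-positive and 335 ± 152 CPM in GFP-negative libraries (SD, n = 3 each), and no member passed over the list alone. Of the metabolic lists, glycolysis and hypoxia (14 of 19 negative, camera adjusted p = 0.0728), cholesterol synthesis (15 of 19 negative, adjusted p = 0.168) and oxidative phosphorylation (19 of 29 negative, adjusted p = 0.437) were not called. Without GFP-positive replicate 3 the glycolysis list had a camera adjusted p of 0.0104 (0.624 with an estimated correlation). It had 0.0213 without GFP-negative replicate 1 (0.867 with an estimated correlation) and 0.038 on log2(TPM + 1) (0.649 with an estimated correlation). The cholesterol list had 0.043 without GFP-negative replicate 3 and 0.0204 without GFP-positive replicate 2. With an estimated correlation these were 0.628 and 0.629.

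T cell identity genes were not called (camera adjusted p = 0.386), and Cd4 had 564 ± 69.9 CPM in GFP-positive and 659 ± 57.3 CPM in GFP-negative libraries (SD, n = 3 each). Of the lists of other cells, the erythroid one was called higher (4 of 5 positive, camera adjusted p = 0.0182), with an adjusted p of 0.661 with an estimated correlation. It had 0.142 without GFP-negative replicate 2, 0.108 without GFP-negative replicate 3, 0.137 without GFP-positive replicate 1 and 0.0796 without GFP-positive replicate 3. Hbb-bs, a beta globin gene, stood at 12.6, 0 and 0 CPM in GFP-negative replicates 1 to 3 and at 30.0, 5.75 and 12.3 CPM in GFP-positive ones.

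Myeloid markers (9 of 9 positive, camera adjusted p = 0.146), epithelial (adjusted p = 0.802), stromal and endothelial (0.386), B and plasma cell (0.114) and CD8 T cell markers (0.386) were not called. Neither were natural killer and antigen-presenting cell markers (0.791 each), whose median and mean were positive while the test pointed lower. The myeloid list had an adjusted p of 0.0051 without GFP-positive replicate 1 and 0.0134 without GFP-positive replicate 2, both higher, and 0.0196, lower, without GFP-positive replicate 3. Without that library the natural killer and antigen-presenting lists were lower with adjusted p of 0.0144 and 0.000382. With an estimated correlation the adjusted p without that library was 0.624 for the myeloid and natural killer lists and 0.602 for the antigen-presenting list. B cell markers had 0.0204 without GFP-negative replicate 3 and 0.038 on log2(TPM + 1), and 0.427 and 0.491 with an estimated correlation. Myeloid markers were higher with no filter (0.0458) and on log2(TPM + 1) (0.0109), with 0.754 and 0.649 with an estimated correlation. The myeloid list had 0.815 without GFP-positive replicate 1 and 0.738 without GFP-positive replicate 2 with an estimated correlation.

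In all, camera called 11 of 30 lists, 6 higher and 5 lower. With an estimated correlation it called 0, with a smallest adjusted p of 0.17 and 2 lists (stem and memory, Wnt targets) at an unadjusted p below 0.05, and fry called 0 for a shift in a single direction and 6 for changes in either direction. Without GFP-positive replicate 3 camera called 13 lists, 9 of them among the 11, and 0 with an estimated correlation. With an estimated correlation it also called 0 lists without any other library, with no filter and on log2(TPM + 1), with smallest adjusted p from 0.195 to 0.611. Some lists share genes, so the 11 calls are not independent of each other. Klrg1 is in the regulatory T cell, cytotoxic and inhibitory receptor lists, and Klrc1 in the latter pair. Tcf7 and Lef1 are in both the stem and memory list and the Wnt list.

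**Figure D3:**
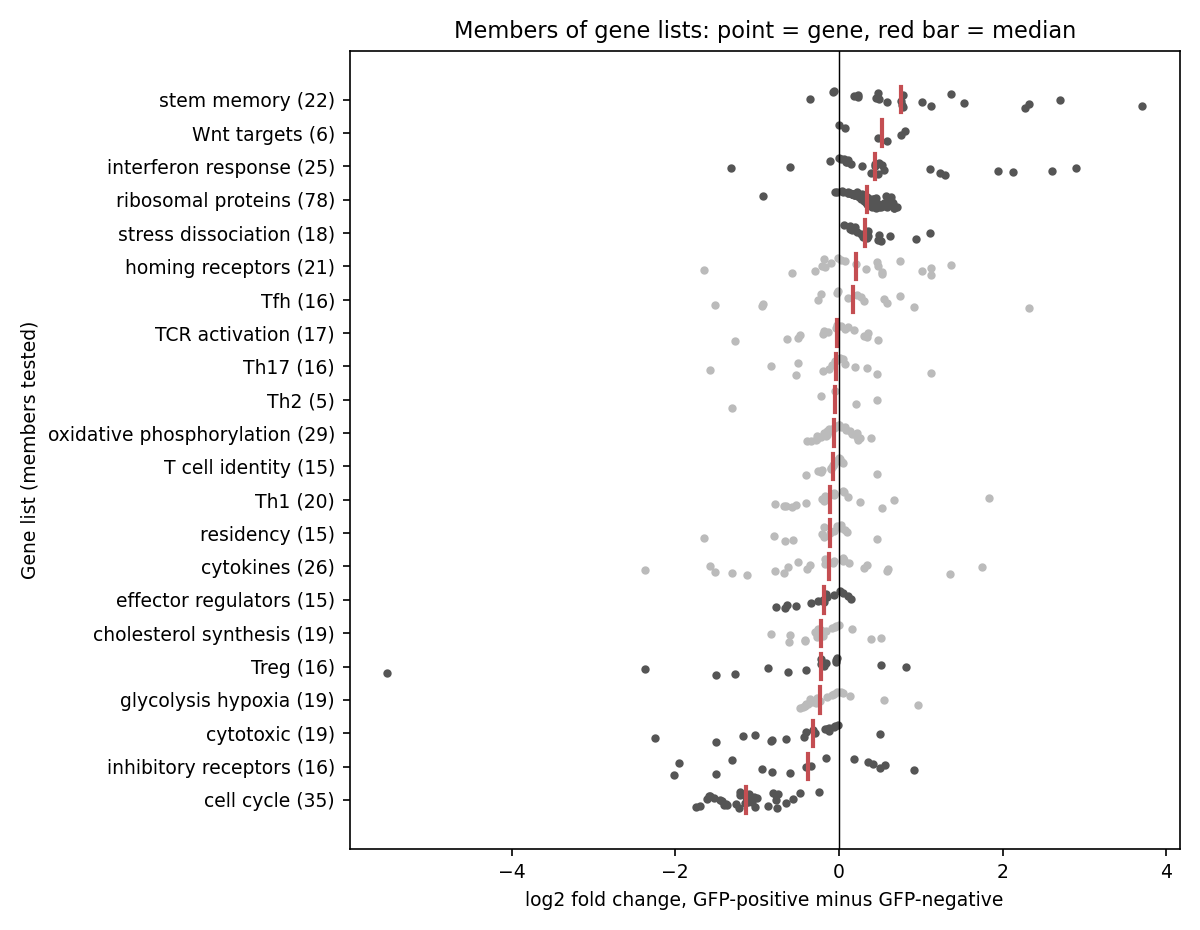
Log2 fold change (GFP-positive minus GFP-negative) of each tested gene in 22 lists of T cell states, metabolism, stress and identity, with a red bar at each list's median; dark points belong to lists called by camera at the preset correlation. The medians run from -1.14 for cell cycle genes to 0.76 for stem and memory genes.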

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

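The limma-voom fit with sample quality weights, the fit with a myeloid covariate, the weighted list test, the list tests without Tcf7, those with an estimated correlation under other settings and the leave-out fits on a fixed set of genes were chosen after seeing the data. The 12 calls became 19 with library size alone, 373 with no filter, 200 with DESeq2, 5 with limma-voom, 48 with the myeloid covariate (14 higher, 34 lower), 1 with limma on log2(TPM + 1), 0 with log2(TPM + 0.1), 0 with log2(TPM + 1) unfiltered and 0 at an adjusted p of 0.01. With RLE factors, the filter of 1 CPM (which kept 12300 genes, more than the default), quality weights and a fold minimum the count stayed within 11 to 15. With no filter, edgeR's median prior degrees of freedom went from 8.64 to infinite, so genes no longer kept a spread of their own, and 305 of the 373 were among the 11074 genes tested in the main analysis; for the other settings the cause was not tested. In 18 of these settings, those on a fixed set of genes not counted, the 12 genes kept their direction. Leaving out a library gave 0 to 42 calls, with the filter applied anew to 11361 to 11866 genes. On the 11074 genes of the full data it gave 10, 5 and 11 calls without GFP-negative replicates 1 to 3 and 0, 3 and 50 without GFP-positive replicates 1 to 3, of which 5, 2, 9, 0, 3 and 12 were among the 12 genes. Tcf7 had a log2 fold change of 0.52 to 0.95 over 18 alternatives, with adjusted p from 0.00314 to 0.77. It passed only with no filter, at 0.75; without 1 library it ranged over 0.52 to 0.95. The count of called lists was 11 in the main test, 0 with an estimated correlation, 0 with fry, and 7 to 13 when a library was left out. The myeloid list was called lower, not higher, without GFP-positive replicate 3 (adjusted p = 0.0196, and 0.624 with an estimated correlation), and its adjusted p ranged from 0.0051 to 0.196 when a library was left out. The share of other-cell markers was higher in GFP-positive cells by 0.478 percentage points of counts and by 0.974 of TPM, and it ranged from -0.0315 to 0.738 when a library was left out. Of 198 values of the 11 named genes that passed the test, 98 no longer passed and none changed sign. Of 2014 values of the 112 others, Tcf7 aside, 88 passed and 47 changed sign without passing. At these depths and this spread, changes of 2-fold were recovered in 32.3% of simulated genes and of 4-fold in 66.0%. With the replicate number as a block, 81 genes were called, 21 higher and 60 lower, all 12 included. Among those lower were Mki67, Top2a, Gzma, Gzmb, Il17a and Cd8a. Among those higher were the stem and memory genes Slamf6, S1pr1, Il7r, Klf3 and Bcl2, beside Id3. In that setting 12 lists were called, inhibitory receptors were not (camera adjusted p = 0.0678), and Tcf7 had 0.78 (edgeR adjusted p = 0.0519). Deviations of same-numbered libraries from their group means correlated at 0.104, 0.0971 and 0.104. Each of the 6 libraries correlated best with its own number (largest other r 0.0195). Deviations from a group mean cancel within the group, so these correlations depend on each other. They are a weak hint from the data and not from the design.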

Other observations

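The tests of the marker lists in GFP-positive replicate 3, of mixing between the gates, of dilution of the cell cycle list by RNA of other cells and of the division of its library scores were chosen after the result was seen.

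Without GFP-positive replicate 3, further genes of T cell differentiation passed edgeR's test. Among lower genes were Havcr2 (log2 fold change -3.79 ± 0.46 SE, adjusted p = 0.00815), Gzma (-3.14 ± 0.54, adjusted p = 0.0474) and Klrc1 (-1.08 ± 0.19, adjusted p = 0.0426). Cebpb, a bZIP transcription factor, had -4.36 ± 0.57 (adjusted p = 0.00815). Among higher genes were Slamf6 (2.46 ± 0.42, adjusted p = 0.0436), S1pr1 (1.25 ± 0.22, adjusted p = 0.0399) and Nt5e, which encodes the ectoenzyme CD73 (1.09 ± 0.15, adjusted p = 0.0144). Cebpb and Nt5e were picked after their values were seen. With all 6 libraries Nt5e had 349 ± 95.2 CPM in GFP-positive and 189 ± 23.5 CPM in GFP-negative libraries (SD, n = 3 each), and Cebpb stood at 0.866, 0.92 and 11.3 CPM in GFP-positive replicates 1 to 3 and at 16.7, 23.4 and 16.7 CPM in GFP-negative ones.

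2 other genes, also picked after their values were seen, differed in level without passing the test on all libraries. Penk, which encodes the opioid precursor proenkephalin, had 68.6 ± 26.1 CPM in GFP-positive and 162 ± 40.7 CPM in GFP-negative libraries (SD, n = 3 each; edgeR adjusted p = 0.143). Siglech, known from plasmacytoid dendritic cells, stood at 31.0, 5.68 and 8.11 CPM in GFP-negative replicates 1 to 3, at 0 in GFP-positive replicates 1 and 2 and at 0.861 CPM in replicate 3 (edgeR adjusted p = 0.118); without replicate 3 it was called lower (adjusted p = 0.0349).

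For the transcripts of other cell types in GFP-positive replicate 3, RNA of such cells in that library is a candidate explanation. In that library 5 of the 8 marker lists lay more than 5-fold above the mean of the other libraries, which restates the pattern and does not test it. Its T cell identity genes had the lowest mean, 9.12 log2 CPM against 9.35 to 9.43. The natural killer list is among the 5 mostly through Tyrobp (487 CPM) and Fcer1g (302 CPM), which myeloid cells also express, while Ncr1 and Klre1 lay within the range of the other libraries and Klra1, Klra3 and Klra9, low in that library, were at 0 in all of those, so natural killer cells stay open, and MHC class II genes and Cd74 are shared with macrophages too. The myeloid list was 42.4 times and the antigen-presenting list 19.2 times that mean, with Lyz2 at 4217 and S100a8 at 1563 CPM, although a sort for CD4 T cells should remove such cells. GFP-positive replicates 1 and 2 averaged 0.0159% myeloid counts, below the highest GFP-negative library at 0.0212%, so they did not share the myeloid transcripts. That was already part of the pattern when it was named, so it does not separately test a property of the GFP-positive cells. Whether the cells were sorted or their RNA was free stays open.

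Tcf7 mRNA differed by 1.69-fold although the gate rests on its reporter. If pure GFP-negative cells had no Tcf7 mRNA and the gates had mixed, no gene higher in GFP-positive cells could differ by more than Tcf7. With a pure GFP-positive gate, 59.3% of the GFP-negative RNA would have to come from GFP-positive cells. A smaller share would do if the gates had mixed both ways. Of 21 other stem and memory genes, 3 had a lower 95% bound above the upper bound of Tcf7 (1.27), namely Id3 (1.59), Slamf6 (1.46) and Nsg2 (2.16). Those bounds rest on a normal approximation, which is too narrow for 3 libraries per group. Nsg2 stood at 1.36, 0.227 and 0.439 CPM in GFP-negative replicates 1 to 3, at or near the level of 3 counts. These are also the highest of 21 genes whose values were already seen, so such mixing as the whole cause is not excluded. The trend of fold changes on exon length and GC content explained 0.92% of their variation, so its removal could move genes little. Removing it moved the log2 fold change of Tcf7 by 0.063, less than its SE of 0.26. The fitted trend thus accounts for little of the change in Tcf7. With a trend this weak a small shift was bound to follow, so it is no separate test of the cause. Mixing of the gates, or Tcf7 mRNA in GFP-negative cells, may remain.

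Cell cycle genes were lower in GFP-positive cells, and less cycling in that gate is a hypothesis. After removing the trend on exon length and GC content the median log2 fold change of the list was -1.18, and without GFP-positive replicate 3 it was -1.19. The lower level thus does not rest on the fitted trend or on that library. A trend explaining 0.92% of the variation could move the median little, so its removal is a weak test. Leaving out GFP-positive replicate 3 covers dilution by RNA of other cells in that library alone. A chance division of libraries whose share of cycling cells varies cannot be told apart from an effect of the gate, since the exact two-sided permutation p of the list score was 0.1, the smallest that 3 against 3 libraries allow. The correlation among members estimated by camera was 0.668.

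The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 12 genes and the highest other split 0, and 1 split, the real one, gave as many. For lists the real split gave 11, and 1 split, the real one, gave as many. Each other split gave 4 to 9 lists, so camera at the preset correlation called lists under every division of the libraries.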
